A study of Mus musculus with 4 samples.

How the data were processed

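The series holds 4 10x Visium Spatial Gene Expression libraries of mouse brain, 1 for each of the guides g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1. Per the labels' protocols, Cas9 mice (strain R26-Cas9-Fezh) aged 12 to 16 weeks received Mok-LV virus meant to delete Sox9, Trps1, both or neither by CRISPR, and brains were taken after 7 days, snap frozen and cut coronally at 10 µm, with 2 sections on each capture area. Per the labels g-Control came from a female and the other libraries from males. Whether both sections of a capture area came from 1 animal, and how many animals were used, is not given in the sources used here. The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and spot, not normalized, which the authors made with Space Ranger 1.2.2 on mm10 per the submitters' processing notes. The annotation, and how reads shared by near-identical genes were counted, are not given in the sources used here. The tables held 21859 genes among 21866 features, the other 7 being guide sequences for the control, Sox9, Trps1 and Zeb1, and 24 symbols were shared by several gene identifiers. Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 stands for, and no genome sequence was used.

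Spots over tissue numbered 2320, 2857, 2386 and 2184 in g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1. Those with at least 500 UMIs, 2252, 2758, 1980 and 1884, were clustered together with scanpy 1.11.5 on 2000 variable genes, of which 1860 were used after 512 listed outcome genes were left out, each gene scaled within its library, with 30 principal components, 15 nearest neighbours and Leiden resolution 1 (igraph 0.11.9). This gave 16 clusters. A cluster took the name of a region where at least 3 markers fixed beforehand were among its 30 leading genes. For cortical clusters the markers of all cortical layers were counted together, and the layer with most of them gave the name. The first form of this rule searched fewer genes and left cortical layers 5 and 6 unnamed, so it was revised once after the clusters were seen. Clusters with very low UMIs relative to the median of their own libraries were left out, whatever genes led them. This rule, applied after seeing the data, removed 17.7, 12.1, 15.9 and 16.8% of clustered spots, beyond the spots already left out for under 500 UMIs. Spots hold several cells, so clusters are called regions, no doublet caller was run and no cell-type makeup was estimated. Cortical spots numbered 859, 1426, 914 and 799, with shares by layer of 32.2, 31.4, 31.2 and 29.8% for layers 2 and 3, 16.4, 18.9, 17.0 and 17.4% for layer 4, 30.2, 23.0, 27.8 and 29.0% for layer 5 and 21.2, 26.7, 24.1 and 23.8% for layer 6. Capture areas were split into section A, nearer the array origin, and section B by 2-means of spot positions, except g-Trps1, whose sections were 2 separate pieces. In g-Control, g-Sox9 and g-Sox9+Trps1 the tissue spots were joined, so the border between A and B may cut through a section. That border was not checked against images, and section pairings and values with a section left out rest on it. Cortical UMIs of sections A and B were 12830775 and 1573605 in g-Control, 8766730 and 6988572 in g-Sox9, 9104178 and 5151852 in g-Trps1, and 3522766 and 3767791 in g-Sox9+Trps1. Median UMIs over all tissue spots of A and B were 15543 and 4170 in g-Control and 8144 and 7516.5 in g-Sox9. In g-Trps1 they were 13564.5 and 1049, and in g-Sox9+Trps1 6268 and 2718.

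UMIs were summed over cortical spots and given as counts-per-million (CPM) values. Median UMIs per cortical spot were 16698, 10843.5, 15055 and 8543, mitochondrially encoded genes took 12.8, 11.4, 12.9 and 10.3% of cortical UMIs, and a count of 0 allows up to 0.208, 0.190, 0.210 and 0.411 CPM (3 counts). With 1 library per group no 2 groups could be tested against each other across libraries. A fit of the 2 guides as additive effects, which leaves 1 residual degree of freedom and rests on their having no interaction, was not run, and no p-value was computed. The fold between 2 libraries has an exact conditional binomial (Clopper-Pearson) 95% interval, which covers counting error only. A gene was counted as higher or lower with at least 100 UMIs in the library with more, a fold of at least 1.5 and a fold of at least 1.25 the same way in all 4 pairings of the sections of one capture area with those of the other. These counts include sex-linked, mitochondrially encoded and blood genes. Section pairings show spread within a capture area, and whether that spread includes a difference between animals is not known. Log2 folds had 0.5 UMI added.

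The comparisons, gene lists, fold rule and rule for named genes were fixed before the data were examined, while the rules that name regions and leave out clusters of low UMIs, which set the cortical spots of every comparison, took their form afterwards. Genes apart in 1 library differ the same way by at least 1.5-fold from each of the other 3, with 100 UMIs in the library with most and no section condition. The named genes are the 10 highest and 10 lowest folds of each guide library over g-Control that met the rule, leaving out sex-linked, mitochondrially encoded, blood and clone-named genes, and the 5 highest and 5 lowest of the other 3 comparisons. To these were added up to 4 members, with 100 UMIs and the largest folds in the direction of the median, of each list outside the random lists, up to 2 members meeting the rule of each other list, the 5 highest and 5 lowest genes apart in 1 library, and always Sox9, Trps1, Gfap, Vim, Aqp4, Slc1a2, Aldh1l1, Aif1, Cd68 and Mbp. Not every gene that the rule takes is printed, and 1 of them is not reported here. The 34 lists, with 650 members of which 640 were in the tables, cover homeostatic and reactive astrocytes, astrocyte transcription factors, synapse regulators secreted by astrocytes, interferon response, antigen presentation, homeostatic microglia, activated microglia and macrophages, lymphocytes and neutrophils, complement, oligodendrocyte precursors, myelin and oligodendrocytes, excitatory and inhibitory neurons, synaptic components, immediate early genes, circadian clock, glucocorticoid response, endothelial cells, mural cells, fibroblasts and meninges, extracellular matrix, cell proliferation, neurogenesis, p53 and DNA damage, endoplasmic reticulum stress, heat shock, cholesterol and lipid synthesis, metallothionein and oxidative stress, ependymal cells, choroid plexus, blood, mitochondrially encoded and sex-linked genes. A list's median log2 fold over members with 20 UMIs was set against 10000 random lists of the same size matched on mean expression in 20 bins, and called outside where it lay beyond the 2.5th or 97.5th percentile, as a description of these libraries.

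The focus of a library was the 5% of cortical spots with the highest share of UMIs of the 2 microglia lists over a spot and its neighbours. For the spread over spots, each cortical spot was thinned to 3500 UMIs. Correlations of folds were set beside 100 simulations of unchanged libraries against the same control. List levels by region and around the control guide were added after seeing the data.

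Calls were tested on simulated counts drawn from the real means and depths. Changed genes were picked among those expected to reach 100 UMIs in either library, while the rule asks this only of the library with more. Draws were Poisson with the same rate in both sections. The shares and calls below thus leave out the real spread between sections and need not hold for the real libraries. Of genes changed 1.5-fold, 56.7% were called for g-Sox9 over g-Control, 39.5% for g-Trps1 over g-Control and 33.3% for g-Sox9+Trps1 over g-Control, and of genes changed 2-fold 97.1, 93.6 and 98.6%. For g-Sox9+Trps1 over g-Sox9, g-Sox9+Trps1 over g-Trps1 and g-Sox9 over g-Trps1 the shares were 43.1, 59.2 and 47.5% at 1.5-fold and 100, 100 and 98.3% at 2-fold. With no gene changed, counting noise alone gave 2, 2, 8, 23, 13 and 5 calls in these 6 comparisons in that order. With no list shifted, 3 of 34, 6 of 34, 1 of 34, 2 of 33, 1 of 33 and 5 of 34 lists fell outside the random lists, and of 5 lists shifted 1.5-fold 5 of 5 did in each comparison.

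Alternatives covered all tissue spots, equal weight per cluster or per spot, listed genes kept in the clustering, joint scaling, no minimum per spot, other gene minimums and fold sizes, no section condition, TMM scaling with edgeR 4.0.16, totals without mitochondrial and blood genes, thinning to equal depth, each section left out in turn, other focus sizes and, added after seeing the data, cortical spots with at least 3000 UMIs. TMM factors were 0.986, 1.00, 0.995 and 1.02. Counts were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3. Regions outside the cortex were used for levels by region, for the alternative over all tissue spots and for tests in the closing observations, and the guide features for the closing observations and for marks on the map of interferon genes.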

Results

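Spatial gene expression was measured in the cortex of adult mice that carry Cas9, 7 days after injection of Mok-LV virus with guide RNAs against the transcription factor genes Sox9, Trps1 or both, or with a control guide. The question the design poses is what loss of these genes in the injected cortex does to the expression of other genes. Each condition was 1 Visium capture area with 2 coronal sections, on which every spot collects the RNA of a small tissue region that holds several cells. The 4 libraries, called g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1, held 27551489, 23613296, 23227677 and 12345692 unique molecular identifiers (UMIs) over 2320, 2857, 2386 and 2184 tissue spots. Comparisons used the 859, 1426, 914 and 799 spots in clusters named as cortical layers, with 14404380, 15755302, 14256030 and 7290557 UMIs. The g-Control library is labelled female and the other 3 male. There were no replicate libraries, so intervals cover counting error only, every comparison is between libraries and not between conditions, and none has a replicate check. A gene was counted as higher or lower in a library where its counts-per-million (CPM) value differed by at least 1.5-fold, and the same way by a smaller fixed fold in all 4 pairings of sections.

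Sox9, a transcription factor gene that marks astrocytes in the adult cortex, and Trps1, which encodes a zinc finger repressor of the GATA family, are the targeted genes. Sox9 (ENSMUSG00000000567.5) lies on chromosome 11 from 112782210 to 112787757 and Trps1 (ENSMUSG00000038679.16) on chromosome 15 from 50654757 to 50890631 of GRCm38.p6. Cortical Sox9 counts were 21.2 CPM in g-Control (306 UMIs), 22.8 in g-Sox9 (360), 23.3 in g-Trps1 (332) and 15.4 in g-Sox9+Trps1 (112). Relative to g-Control, Sox9 was at 1.08-fold [0.921, 1.26] in g-Sox9, 1.1-fold [0.936, 1.28] in g-Trps1 and 0.723-fold [0.577, 0.901] in g-Sox9+Trps1, with exact conditional 95% intervals in brackets. Trps1 counts were 13.5 CPM in g-Control (195 UMIs), 11.3 in g-Sox9 (178), 12.9 in g-Trps1 (184) and 11.7 in g-Sox9+Trps1 (85), or 0.835-fold [0.677, 1.03], 0.953-fold [0.775, 1.17] and 0.861-fold [0.660, 1.12] of g-Control. Thus Sox9 was not lower in the library labelled g-Sox9, Trps1 was not detectably lower in the library labelled g-Trps1 at this depth, and Sox9 alone was below g-Control beyond counting error in the library labelled g-Sox9+Trps1. In that library Trps1 stood at 8.80 CPM in section A and 14.3 CPM in section B, and its fold over g-Control ran from 0.650 to 1.06 with single sections left out. Virus may reach only a part of the cells in a spot, which was not measured. A small deletion in the coding sequence need not remove the transcript end that is counted, so these counts do not check the labels. The groups are therefore named as labelled throughout.

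**Figure D1:**
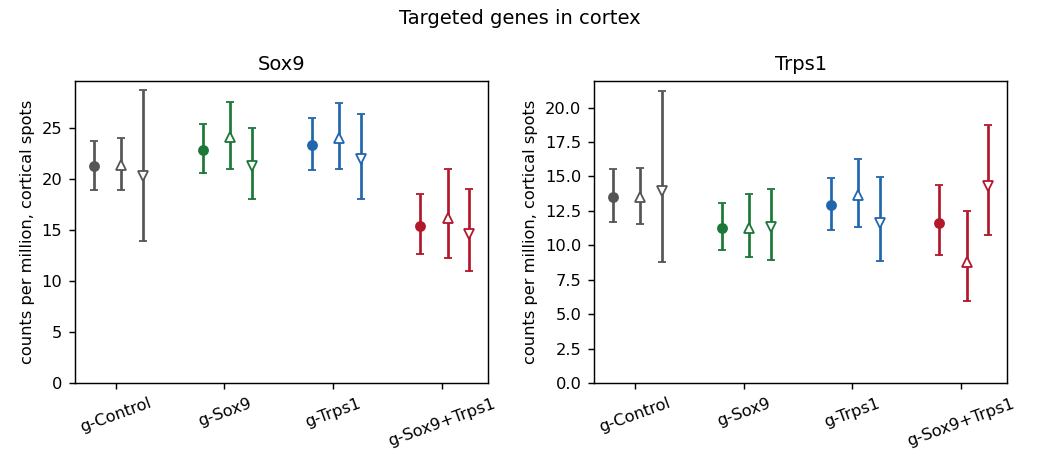
Cortical Sox9 (left) and Trps1 (right) in CPM by library, with filled circles for both sections, upward triangles for section A, downward triangles for section B and bars for exact Poisson 95% intervals. Sox9 reads 21.2, 22.8, 23.3 and 15.4 CPM from left to right, and Trps1 13.5, 11.3, 12.9 and 11.7 CPM.

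In the cortical spots of the g-Sox9 library, genes that neurons transcribe within minutes of activity were lower than in g-Control. These spots leave out a low-UMI cluster led by Nr4a1, with Arc and Dusp1 among its leading genes. That cluster held 15.1% of clustered spots in g-Control and 7.11% in g-Sox9. Of 20 immediate early genes with 100 UMIs, 13 were lower and the list median was -0.83 on the log2 scale, below the central 95% of random lists of matched expression. Egr2 was 8.65-fold lower [5.54, 14.2], Fos 4.38-fold [3.79, 5.08], Nr4a1 4.15-fold [3.76, 4.58], Arc, a synaptic plasticity gene, 3.32-fold [3.04, 3.64], Nr4a3 2.84-fold and Junb 2.63-fold. The 10 lowest genes also held Per1, a circadian clock gene, at 2.62-fold lower, the phosphatase gene Dusp1 at 2.60-fold, Csrnp1 at 2.52-fold and Midn at 2.5-fold. Clock genes had a median of -0.21, with 4 of 16 lower, among them Per2 at 2.30-fold, Ciart at 2.07-fold and Bhlhe40 at 1.58-fold. Glucocorticoid response genes had a median of -0.36, with 4 of 11 lower, among them Sgk1 at 1.70-fold and Cdkn1a at 1.53-fold. Over all tissue spots Cdkn1a and Bhlhe40 were only 1.11-fold and 1.34-fold lower, and Cdkn1a ended at 1.47-fold or less in 4 other settings. Without g-Control section A, Csrnp1 was 1.59-fold and Egr2 13.7-fold lower, and Egr2 was 14.1-fold lower without g-Sox9 section A.

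The lists of resting and of reactive astrocyte genes had medians below the random lists in g-Sox9. The 34 genes of resting astrocytes had a median of -0.16, with 1 member past the 1.5-fold rule, and Aqp4 (the main water channel of astrocyte endfeet), Aldh1l1 and the glutamate transporter gene Slc1a2 were at 0.827-fold, 0.851-fold and 0.871-fold of g-Control. Reactive astrocyte genes had a median of -0.12, over section pairings from -0.15 to 0.04. Within that list the intermediate filament genes Gfap and Vim were 1.68-fold [1.56, 1.81] and 1.96-fold [1.69, 2.28] lower, and Serpina3n was 1.99-fold lower [1.72, 2.31]. The metal-binding metallothionein genes Mt2, Mt1 and Mt3 were 2.09-fold, 1.76-fold and 1.55-fold lower, while their wider list on oxidative stress had a median of -0.09. Synapse regulators secreted by astrocytes had a median of -0.17, with Lrp4 1.76-fold lower. Medians were -0.14 for extracellular matrix genes, among them Hapln1 at 1.51-fold lower, -0.16 for complement and -0.06 for homeostatic microglia, among them Fcrls at 1.92-fold lower. Cd68, a lysosomal gene of phagocytes, and Lyz2 were 1.53-fold and 1.81-fold lower. Over all tissue spots Cd68 was 1.27-fold lower, with equal weight per spot Hapln1 was 1.39-fold lower, and without g-Control section A Cd68 and Mt3 were 1.48-fold and 1.43-fold lower.

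Higher in g-Sox9 were Ttr at 3.26-fold [3.16, 3.36], Folr1 at 3.89-fold [2.56, 6.09] and Ecrg4 at 2.31-fold [1.64, 3.32], genes abundant in the choroid plexus, and the striatal phosphodiesterase gene Pde10a at 1.95-fold [1.67, 2.28]. The other 6 of the 10 highest, Oprk1, Kcnj2, Cmya5, Syndig1l, Arhgap22 and Bid, lay between 2.29-fold and 1.83-fold. Pde10a was among the highest genes of g-Trps1 too, which held only 71 striatal spots. Choroid plexus genes had a list median of 0.95 and a summed fold of 3.24, and this library held 165 ventricle and choroid plexus spots and 344 striatal spots against 49 and 82 in g-Control, and 21 hippocampal spots against 287, 215 and 185 in g-Control, g-Trps1 and g-Sox9+Trps1, so the regions on its sections differed. Medians were above the random lists for antigen presentation at 0.16, with Psmb8 1.70-fold higher, myelin at 0.14, with Aspa 1.66-fold higher, mural cells at 0.33 and cell proliferation at 0.37. Sex-linked genes followed the labels, with Ddx3y at 594, 538 and 196 UMIs in g-Sox9, g-Trps1 and g-Sox9+Trps1 and 0 in g-Control, and a list median of 3.32 in g-Sox9. Mitochondrially encoded genes had a median of -0.25, with mt-Atp8 1.97-fold and mt-Nd4l 1.76-fold lower, though both overlap a neighbouring gene, and blood genes a median of 0.36. Altogether 38 genes were higher and 94 lower of 10464 with 100 UMIs, with 3 sex-linked genes among the higher and 3 mitochondrially encoded among the lower. Section B of g-Control alone held 178 cortical spots and 1573605 UMIs. Folds without g-Control section A therefore rest, here and throughout, on few g-Control UMIs for genes of low counts. Folr1 and Oprk1 had only 28 and 44 g-Control UMIs over both sections. Without section A of g-Control, which holds most of its cortical UMIs, the counts were 402 and 300, Psmb8 stood at 3.46-fold, Folr1 at 5.94-fold, Oprk1 at 5.49-fold, Arhgap22 at 3.56-fold, Syndig1l at 3.42-fold and Cmya5 at 3.30-fold, and the blood and mural medians turned to -0.36 and -0.07, with medians of -0.51 for complement, -0.39 for synapse regulators, 0.32 for myelin, 0.51 for antigen presentation, 0.83 for proliferation, 1.53 for choroid plexus, -0.12 for mitochondrially encoded and 1.99 for sex-linked genes. Without g-Sox9 section B, Ttr stood at 1.61-fold, Folr1 at 1.94-fold, Ecrg4 at 1.33-fold and Gfap at 0.681-fold of g-Control, homeostatic microglia turned to 0.08, and medians were 0.35 for choroid plexus, 0.05 for myelin and -0.13 for clock genes. Over all tissue spots Gfap was at 0.745-fold, Bid at 1.45-fold and Syndig1l at 3.18-fold, with equal weight per cluster Aspa was at 1.33-fold, and without g-Sox9 section A the antigen presentation median was -0.25, Ttr 5.34-fold, Folr1 6.33-fold, Ecrg4 3.55-fold, Psmb8 1.34-fold and medians -0.06 for extracellular matrix, -0.20 for homeostatic microglia, -0.18 for oxidative stress and 0.14 for proliferation. The reactive astrocyte median was -0.02 without g-Control section B.

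In the g-Trps1 library, genes of the interferon response and of antigen presentation were lower than in g-Control. Whether the sections of g-Trps1, or of g-Sox9, held less of the injection site, which could lower such genes, was not tested. Iigp1, an interferon-inducible GTPase gene, was 7.35-fold lower [4.65, 12.2], Ifi27l2a 3.49-fold [2.80, 4.37] and Irgm1 2.47-fold [2.08, 2.95], with 5 of 17 interferon genes lower and a list median of -0.52 (section pairings -1.12 to 0.00). Of 15 antigen presentation genes 6 were lower, with a median of -0.87 (section pairings -1.31 to -0.27), among them Cd74, the invariant chain of MHC class II, at 4.18-fold [3.49, 5.03], H2-Aa at 3.06-fold [2.29, 4.14] and H2-Eb1 at 2.34-fold. C4b of the complement list was 2.08-fold lower [1.82, 2.37] with a list median of -0.27, and medians were -0.20 for activated microglia and macrophages, -0.12 for homeostatic microglia and -0.11 for reactive astrocytes. Gfap was at 0.777-fold, Vim at 0.984-fold, Aif1, a microglial marker, at 0.964-fold and Cd68 at 0.730-fold of g-Control, none of them past the rule.

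Immediate early genes were lower in g-Trps1 too, with 9 of 20 lower and a median of -0.51, among them Egr2 at 3.59-fold [2.59, 5.05], Fos at 3.0-fold [2.64, 3.42], Junb at 2.33-fold and Dusp5 at 1.80-fold. Not all of the list lay lower: Egr3 stood at 103 CPM in g-Control and 164 CPM in g-Trps1, without meeting the section condition. Clock genes had a median of -0.22, with 4 of 16 lower, among them Per1 at 2.52-fold, Ciart at 2.05-fold, Per2 at 1.94-fold and Bhlhe40 at 1.76-fold, and glucocorticoid response genes a median of -0.18, with Sgk1 2.11-fold and Nfkbia 1.56-fold lower. Resting astrocyte genes had a median of -0.03, inside the random lists, with Aqp4 at 1.1-fold and Slc1a2 at 1.04-fold. The highest genes were Ptpn21 at 2.28-fold [1.60, 3.31], Nxpe4 at 2.09-fold, Pde10a at 2.09-fold [1.79, 2.44] and Prdm16, a zinc finger transcription factor gene, at 1.99-fold [1.43, 2.78], and the other 6 of the 10, Urb1, Iqgap2, Dmpk, Mplkip, Parvb and Ptpru, lay between 1.77-fold and 1.57-fold. Medians above the random lists were 0.18 for myelin, 0.20 for fibroblasts and meninges, 0.20 for blood and 3.32 for sex-linked genes. In all, 16 genes were higher, 3 of them sex-linked, and 45 lower of 10311, and Mbp, the myelin basic protein gene, was at 1.2-fold.

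Several of these values changed with single sections left out. Without g-Control section A the counts were 301 higher and 206 lower, Iigp1 was at 0.580-fold of g-Control, Irgm1 at 0.610-fold, Egr2 at 0.177-fold, Ptpn21 at 1.43-fold, Iqgap2 at 1.41-fold, Nxpe4 at 3.42-fold and Dmpk at 3.04-fold, the fibroblast and blood medians turned to -0.31 and -0.51, and medians were -0.49 for antigen presentation, -0.38 for reactive astrocytes, 0.31 for myelin and 2.02 for sex-linked genes. Without g-Trps1 section A, Ifi27l2a stood at 0.0982-fold and C4b at 0.294-fold, with medians of -0.53 for complement, -0.37 for glucocorticoid response, -0.31 for homeostatic microglia, 0.47 for fibroblasts, 0.41 for blood and 0.10 for myelin. The interferon median ran from -1.06 to -0.20 with single sections left out. Without g-Trps1 section B the reactive astrocyte median was 0.01 and those of complement, homeostatic and activated microglia -0.12, -0.05 and -0.04, and Nfkbia and Ptpru were at 0.677-fold and 1.44-fold. Over all tissue spots 8 of the 10 highest genes fell short of the rule, with Parvb at 1.05-fold, Iqgap2 at 1.2-fold, Dmpk and Prdm16 at 1.29-fold, Urb1 at 1.33-fold, Ptpru at 1.34-fold, Mplkip at 1.41-fold and Pde10a at 1.46-fold, and H2-Aa and Iigp1 were at 0.522-fold and 0.208-fold.

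With both genes targeted, interferon and antigen presentation genes were higher than in g-Control. Of 19 interferon genes 12 were higher, with a median of 0.99 (section pairings 0.56 to 1.47), and of 15 antigen presentation genes 9 were higher, with a median of 1.02 (0.53 to 1.33). The T cell chemokine genes Cxcl9 and Cxcl10 were 23.7-fold [13.2, 47.0] and 5.99-fold [4.74, 7.62] higher, with 144 against 12 UMIs for Cxcl9, the ubiquitin-like gene Isg15 5.20-fold [4.13, 6.59], Ccl5 4.44-fold [3.18, 6.25], Ccl12 3.17-fold and the GTPase gene Gbp2 3.08-fold. The MHC class II genes H2-Ab1, H2-Eb1, H2-Aa and Cd74 were 4.53-fold [3.75, 5.49], 4.12-fold, 3.90-fold [3.28, 4.66] and 2.97-fold [2.69, 3.30] higher. Ccn1 and the immediate early gene Btg2 were 3.88-fold [2.80, 5.44] and 2.67-fold higher, the immediate early list had a median of 0.05 with 5 of 21 higher, and activated microglia and macrophages had a median of 0.33. Myelin genes had a median of 0.28 (section pairings 0.01 to 0.70), with Opalin 1.75-fold and Aspa 1.66-fold higher.

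Lower in g-Sox9+Trps1 were Gfap at 1.72-fold [1.56, 1.90], the glutamine synthetase gene Glul at 1.61-fold [1.54, 1.69] and Mertk, a receptor for engulfment, at 2.07-fold, while resting astrocyte genes had a median of -0.13, Vim was at 0.734-fold, Aqp4 at 0.833-fold, Slc1a2 at 0.856-fold and Aldh1l1 at 1.01-fold, and reactive astrocyte genes had a median of 0.03. Synapse regulators of astrocytes had a median of -0.10, with Lrp4 1.86-fold and Chrdl1 1.66-fold lower. The synaptic scaffold genes Shank3 and Shank1 were 2.12-fold [1.72, 2.62] and 1.61-fold lower and the glutamate receptor gene Grin2b 1.62-fold, with medians of -0.04 for synaptic components and for excitatory neurons. Gstp1 was 6.11-fold lower [4.92, 7.68], Hmga1 4.37-fold, Erh 3.55-fold and Rpl35 2.63-fold, all genes with near-identical copies or pseudogenes, so that their values are uncertain. Also among the 10 lowest, Mapkapk5, Fam173a, C1ql3, Syap1 and Polr2l lay between 3.19-fold and 2.37-fold lower. Medians below the random lists were -0.26 for glucocorticoid response, -0.08 for clock genes, -0.14 for endothelial cells, with Vwf 1.52-fold lower, and -0.79 for choroid plexus genes, with Ttr 1.78-fold lower. Mitochondrially encoded genes had a median of -0.40, with mt-Atp8 2.66-fold and mt-Nd4l 2.20-fold lower. Blood genes had a median of 1.17 and a summed fold of 2.11, with Hbb-bt, Hba-a2 and Hbb-bs, near-identical within each globin family and so uncertain gene by gene, at 2.38-fold, 2.25-fold and 2.09-fold, and sex-linked genes a median of 3.08.

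Here 57 genes were higher and 103 lower of 10165. The higher held 2 sex-linked and 3 blood genes, and the lower 1 sex-linked and 5 mitochondrially encoded genes. The microglial genes Aif1 and Cd68 were at 1.22-fold and 0.923-fold. With the listed genes kept in the clustering that sets the cortical spots, 46 cortical spots of g-Sox9+Trps1 and 23, 3 and 5 of g-Control, g-Sox9 and g-Trps1 fell into an unnamed cluster led by interferon genes and so left the comparison. In that clustering, where other spots also changed region and the cause of lower folds was not isolated, Cxcl9 was at 11.1-fold, Isg15 at 3.0-fold, Gbp2 at 2.03-fold, Cxcl10 at 1.62-fold, Ccl5 at 1.45-fold and the interferon median at 0.54. Over all tissue spots Cxcl9 was at 11.9-fold, Gfap at 0.795-fold, Vwf at 0.794-fold and Chrdl1 at 0.722-fold, with no spot minimum Cxcl10 and Ccl5 were at 3.59-fold and 2.55-fold, and with equal weight per spot Ttr was at 0.675-fold. With equal weight per cluster Gfap was at 0.752-fold, Grin2b at 0.704-fold, and Opalin and Aspa ended below the rule. Without g-Control section A the counts were 241 higher and 160 lower, Cxcl10 was at 15.7-fold, Gbp2 at 7.01-fold, Ccl12 at 5.96-fold, Ccn1 at 6.04-fold, Hbb-bt at 1.38-fold, Hba-a2 at 1.35-fold and Hbb-bs at 1.34-fold, with medians of 0.13 for activated microglia, -0.36 for synapse regulators, -0.14 for clock, -0.38 for choroid plexus, 0.38 for blood and 1.88 for sex-linked genes. Without g-Sox9+Trps1 section B 230 genes were lower and Gfap and Glul were at 0.731-fold and 0.669-fold of g-Control, with medians of 0.50 for activated microglia, 0.51 for myelin, -0.06 for resting astrocytes, -0.14 for excitatory neurons, -0.09 for synaptic components and -0.07 for glucocorticoid response. Without section A of that library the interferon, antigen presentation and myelin medians were 0.62, 0.53 and 0.03, resting astrocytes -0.22, synaptic components 0.02 and choroid plexus -1.32, Cd74 was at 1.94-fold, Grin2b at 0.669-fold, Opalin at 1.36-fold and Aspa at 1.41-fold.

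**Figure D2:**
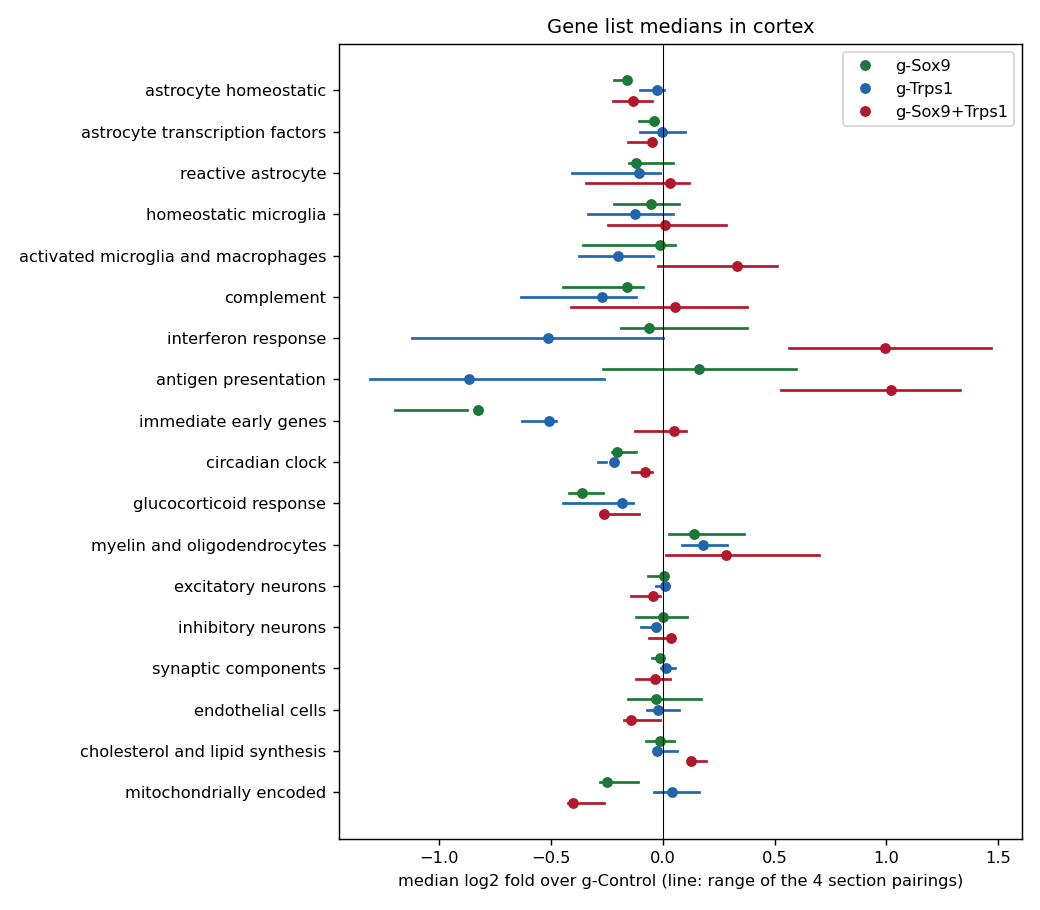
Median log2 fold over g-Control of 18 gene lists in cortical spots for g-Sox9 (green), g-Trps1 (blue) and g-Sox9+Trps1 (red), with lines for the range of the 4 section pairings. Interferon response and antigen presentation lie at 0.99 and 1.02 in g-Sox9+Trps1 and at -0.52 and -0.87 in g-Trps1, and immediate early genes at -0.83 in g-Sox9.

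Set against each single guide, the g-Sox9+Trps1 library was again higher in chemokine, interferon and MHC class II genes. Over g-Sox9, Cxcl9 was 156-fold higher [42.3, 1297] from 144 against 2 UMIs, Ccl5 23.4-fold [12.6, 48.1] and Cxcl10 20.3-fold [14.0, 30.4], and the interferon and antigen presentation medians were 0.96 (11 of 19 higher) and 0.86 (6 of 15). Over g-Trps1, Cxcl9 was 56.3-fold higher [23.6, 176], Cxcl10 25.9-fold [16.8, 41.9], Iigp1 16.8-fold [10.6, 27.7], Cd74 12.4-fold [10.4, 14.9] and H2-Aa 11.9-fold [9.14, 15.9], with medians of 1.70 (16 of 19 higher) and 1.89 (12 of 15). Immediate early genes were higher in g-Sox9+Trps1 than in g-Sox9, with a median of 1.29 (12 of 20 higher), Arc at 5.85-fold [5.34, 6.41] and Nr4a1 at 5.50-fold, and than in g-Trps1, with a median of 0.81 (11 of 20 higher, 3 lower) and Fos at 3.66-fold. Activated microglia and complement genes had medians of 0.23 and 0.32 over g-Sox9 and of 0.36 and 0.39 over g-Trps1. With g-Sox9+Trps1 section A left out they were 0.17 and 0.10 over g-Sox9, where the interferon median was 0.51, and 0.10 and 0.14 over g-Trps1, with its section B left out 0.45 and 0.64 over g-Sox9, and with g-Trps1 section A left out 0.72 and 0.84 over g-Trps1. Ccn1, which encodes a matrix protein, was 6.37-fold and 3.84-fold higher. With the listed genes kept in the clustering, which takes the spots of the interferon-led cluster out of the cortex, Cxcl9, Ccl5 and Cxcl10 were at 49.9-fold, 10.1-fold and 7.08-fold over g-Sox9 and Cxcl10 at 16.6-fold over g-Trps1, and over all tissue spots Cxcl9 was at 50.8-fold over g-Sox9 and 31.8-fold over g-Trps1 and Ccl5 at 11.6-fold over g-Sox9. Without g-Sox9 section A Ccl5 was at 57.0-fold, without g-Sox9 section B Cxcl9 at 86.6-fold, without g-Trps1 section A Cxcl10 at 103-fold over g-Trps1, and without g-Sox9+Trps1 section A Cd74 at 8.13-fold over g-Trps1; equal weight per cluster raised Cxcl9 to 355-fold and 118-fold and Cxcl10 to 30.9-fold and 46.4-fold.

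Lower in g-Sox9+Trps1 than in g-Sox9 were Ttr at 5.79-fold [5.50, 6.11], Folr1 at 5.51-fold, Gstp1 at 2.79-fold and Kcnj2 at 2.33-fold, and choroid plexus genes had a median of -2.63. Without g-Sox9 section B, Ttr and Folr1 were 2.85-fold and 2.74-fold lower, with a choroid plexus median of -1.68, without its section A 9.48-fold and 8.97-fold, and without g-Sox9+Trps1 section B Folr1 and Kcnj2 were 8.87-fold and 4.22-fold lower. Lower than in g-Trps1 were Gstp1 at 5.69-fold [4.58, 7.16], Hmga1 at 4.62-fold, Mapkapk5 at 3.55-fold, Erh at 3.50-fold, Inhba, an activin subunit gene, at 3.40-fold, Mertk at 2.13-fold and Shank3 at 1.91-fold. Sox9 was at 0.672-fold [0.539, 0.833] of g-Sox9, short of the 1.5-fold rule, and 1.52-fold lower [1.22, 1.90] than in g-Trps1, which ended at 0.70-fold without g-Trps1 section A, 0.695-fold without g-Sox9+Trps1 section B, 0.684-fold over all tissue spots and 0.720-fold with listed genes kept in the clustering, and Trps1 was at 1.03-fold of g-Sox9 and 0.903-fold of g-Trps1. Excitatory neuron genes had medians of -0.05 and -0.07, and synaptic components -0.07 over g-Trps1, with 4 of 26 lower. Over g-Trps1 the excitatory median ran from -0.15 without g-Trps1 section A to -0.01 without its section B, and that of synaptic components was -0.02 without g-Sox9+Trps1 section A. Mitochondrially encoded genes had medians of -0.22 and -0.39 and blood genes of 0.72 and 0.92. Over g-Sox9, 72 genes were higher and 51 lower of 10401, and 157 and 180 without g-Sox9+Trps1 section B, where the excitatory median was -0.12 against 0.01 without section A. Over g-Trps1, 94 genes were higher and 101 lower of 10197, or 48.2% higher, against 36.0% (76 and 135) with totals that leave out mitochondrial and blood genes and 38.6% (80 and 127) with TMM scaling; without g-Sox9+Trps1 section B there were 165 and 273.

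Between the single guides, interferon and antigen presentation genes were higher in g-Sox9 than in g-Trps1. The interferon median was 0.44 with 7 of 17 higher and the antigen presentation median 0.87 with 7 of 15 higher, and Iigp1 was 4.96-fold higher [3.09, 8.31], Cd74 4.03-fold [3.37, 4.85], H2-Eb1 3.66-fold, Igtp 3.52-fold and H2-Ab1 3.50-fold. Lower in g-Sox9 were immediate early genes, with a median of -0.58 and 8 of 19 lower, among them Nr4a1 at 2.40-fold, Arc at 2.09-fold and Nr4a3 at 1.72-fold, and the metallothionein gene Mt2 at 2.13-fold [2.01, 2.27]. Hmga1, Polr2l and Syap1 were 2.52-fold [2.0, 3.19], 2.39-fold and 2.10-fold lower. Resting astrocyte genes had a median of -0.13, synapse regulators of astrocytes -0.13 and homeostatic microglia 0.12, and Vim was at 0.517-fold without meeting the rule. Proliferation genes had a median of 0.65, with Mcm5, a subunit of the replicative helicase, 1.57-fold higher. Choroid plexus genes had a median of 0.94 (section pairings -0.51 to 1.94), blood genes 0.16 and mitochondrially encoded genes -0.24. In all 53 genes were higher and 54 lower of 10464, with 150 higher without g-Trps1 section A, where H2-Ab1 was at 8.60-fold, Nr4a3 at 0.668-fold and medians were 1.17 for interferon, -0.05 for resting astrocytes, 0.32 for homeostatic microglia and 0.03 for blood genes, against 0.27 for interferon and 0.26 for blood without g-Trps1 section B, with Mcm5 at 1.36-fold after thinning and Nr4a3 at 0.352-fold over all tissue spots, and without g-Sox9 section A the medians were -0.05 for homeostatic microglia, 0.42 for proliferation and 1.63 for choroid plexus, which was 0.00 without g-Sox9 section B.

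Some genes stood apart from all 3 other libraries by at least 1.5-fold in 1 library, counted here without the section condition. In g-Sox9+Trps1 there were 66, 39 of them higher, led by Cxcl9 (0.833, 0.127, 0.351 and 19.8 CPM in g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1), Cxcl10 (6.66, 1.97, 1.54 and 39.9 CPM) and Isg15 (7.15, 7.93, 7.86 and 37.2 CPM). Its lower genes included Gstp1 (74.6, 34.1, 69.5 and 12.2 CPM), Erh (69.6, 38.7, 68.7 and 19.6 CPM) and Shank3 (32.8, 28.5, 29.6 and 15.5 CPM). In g-Trps1 there were 26, 22 of them lower, among them Cd74 (43.7, 42.1, 10.5 and 130 CPM), Igtp (34.4, 37.5, 10.7 and 85.0 CPM) and Tap1, a peptide transporter of the MHC class I pathway (13, 14.5, 4.98 and 29.8 CPM). Its higher genes included Inhba (6.32, 6.98, 12.1 and 3.57 CPM) and the activity-induced gene Egr3 (103, 98.0, 164 and 104 CPM). In g-Sox9 there were 22, 16 of them lower, among them Nr4a1 (133, 32.0, 76.7 and 176 CPM), Arc (136, 41.0, 85.5 and 240 CPM) and Egr2 (12.1, 1.40, 3.37 and 8.09 CPM), with Ttr higher (375, 1224, 469 and 211 CPM). In g-Control there were 10, with the potassium channel gene Kcna1 (24.0, 11.4, 15.4 and 10.6 CPM) higher and the opioid receptor gene Oprk1 (3.05, 6.98, 5.68 and 8.09 CPM) lower. With the section condition held against each other library, 48 genes stayed apart in g-Sox9+Trps1 (30 higher), 11 in g-Trps1 (0 higher), 13 in g-Sox9 (3 higher) and 7 in g-Control (3 higher), and Igtp, Tap1, Inhba, Egr3, Ttr and Oprk1 did not meet it. Without single sections the numbers with no section condition reached 279 for g-Control (its section A), 83 for g-Trps1 (its section A) and 179 for g-Sox9+Trps1 (its section B).

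The g-Sox9+Trps1 library was compared with the sum of the log2 folds of the single guides. Its interferon genes lay 1.59 above that sum as a median, antigen presentation genes 1.76, immediate early genes 2.0 and activated microglia and macrophages 0.95, and choroid plexus genes lay at -2.92. The immediate early departure comes from low values in g-Sox9 and g-Trps1, since the list median of g-Sox9+Trps1 lay close to g-Control. Low values in g-Trps1 also add to the interferon and antigen presentation departures. High choroid plexus values in g-Sox9, with 165 ventricle and choroid plexus spots against 49 in g-Control, add to that departure. Sex-linked genes, which differ by the label of g-Control alone, lay furthest of all lists from the sum, at -3.65, so whatever is particular to the g-Control library also appears here as a departure. This compares 4 libraries and is no test of an interaction.

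The difference in interferon genes varied by region. In g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1 the summed list stood at 346, 448, 273 and 553 CPM in layers 2 and 3, at 303, 235, 228 and 302 CPM in layer 4, at 512, 519, 292 and 890 CPM in layer 5 and at 414, 352, 244 and 1055 CPM in layer 6, where the g-Sox9+Trps1 interval was [1010, 1102]. In white matter it stood at 836, 855, 448 and 1993 CPM and in thalamus and habenula at 182, 157, 171 and 188 CPM. Reactive astrocyte genes stood at 3356, 3203, 3240 and 4701 CPM in white matter and at 845, 805, 767 and 933 CPM in layer 6. With every cortical spot thinned to 3500 UMIs, the 99th percentile of interferon UMIs per 10000 was 22.9, 22.9, 14.3 and 67.0, that of antigen presentation 34.3, 40, 17.1 and 71.4, and that of reactive astrocyte genes 31.4, 25.7, 31.4 and 31.4. Interferon medians lay at the 2.86 that 1 UMI is worth and were not compared, and medians were 5.71, 5.71, 5.71 and 8.57 for antigen presentation and 5.71 in every library for reactive astrocyte genes. Thinning left out 7, 38, 8 and 59 spots. Without thinning, the 99th percentile of antigen presentation was 27.9 in g-Control and 16.0 in g-Trps1.

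**Figure D3:**
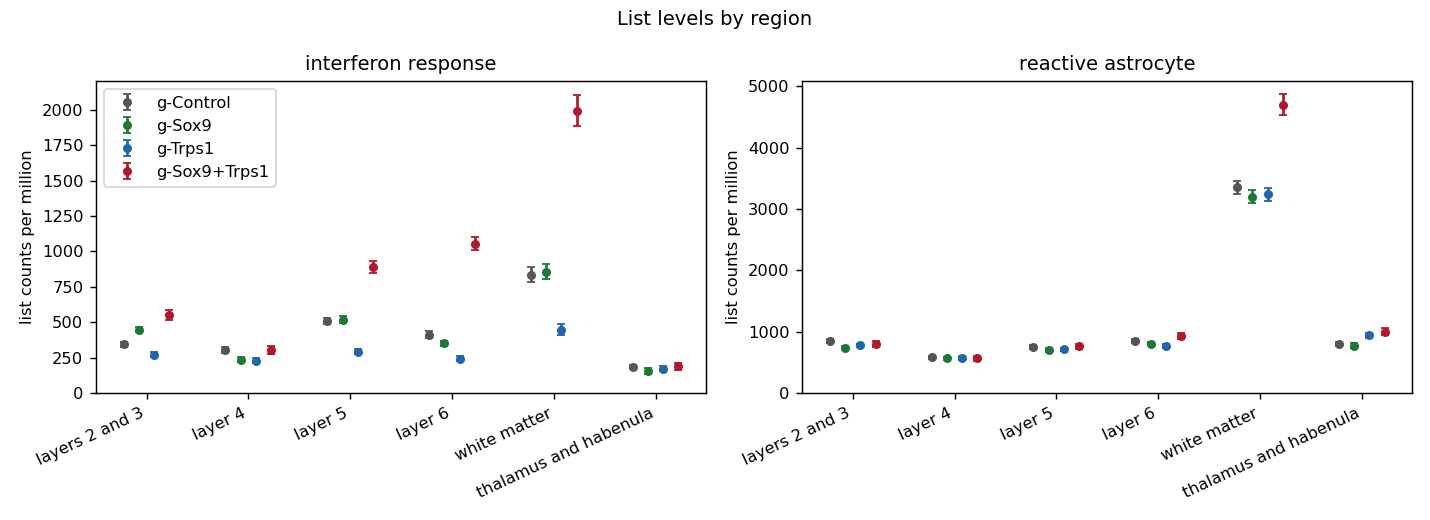
Summed interferon response genes (left) and reactive astrocyte genes (right) in CPM by region and library, with exact Poisson 95% intervals as bars. In g-Sox9+Trps1 interferon genes reach 1993 CPM in white matter and 1055 CPM in layer 6 but 302 CPM in layer 4, where g-Control has 303 CPM.

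Within each library, the 5% of cortical spots with the highest microglial gene share, 43, 71, 46 and 40 spots, were taken as its focus. Ranking by microglial genes favours spots rich in other immune genes, and no measurement placed the focus at the injection site. The focus was richer than other cortical spots in interferon genes by a log2 fold of 1.5 [1.38, 1.62] in g-Control, 1.82 [1.71, 1.93] in g-Sox9, 1.15 [1.0, 1.31] in g-Trps1 and 2.63 [2.53, 2.73] in g-Sox9+Trps1. Antigen presentation genes gave 1.52, 1.77, 0.97 and 2.13, and lymphocyte and neutrophil genes 2.26, 1.63, 2.05 and 3.39. Reactive astrocyte genes gave 1.35 [1.26, 1.43], 0.92 [0.81, 1.02], 1.32 [1.23, 1.41] and 1.15 [1.0, 1.30]. Myelin genes were poorer in the focus of g-Control, g-Sox9 and g-Trps1, at -0.97, -0.52 and -0.76, and richer in that of g-Sox9+Trps1, at 0.46. The foci may thus not lie in like tissue, which limits comparing their values between libraries. Over 2% of spots the reactive astrocyte values were 1.67, 1.08, 1.65 and 1.64.

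**Figure D4:**
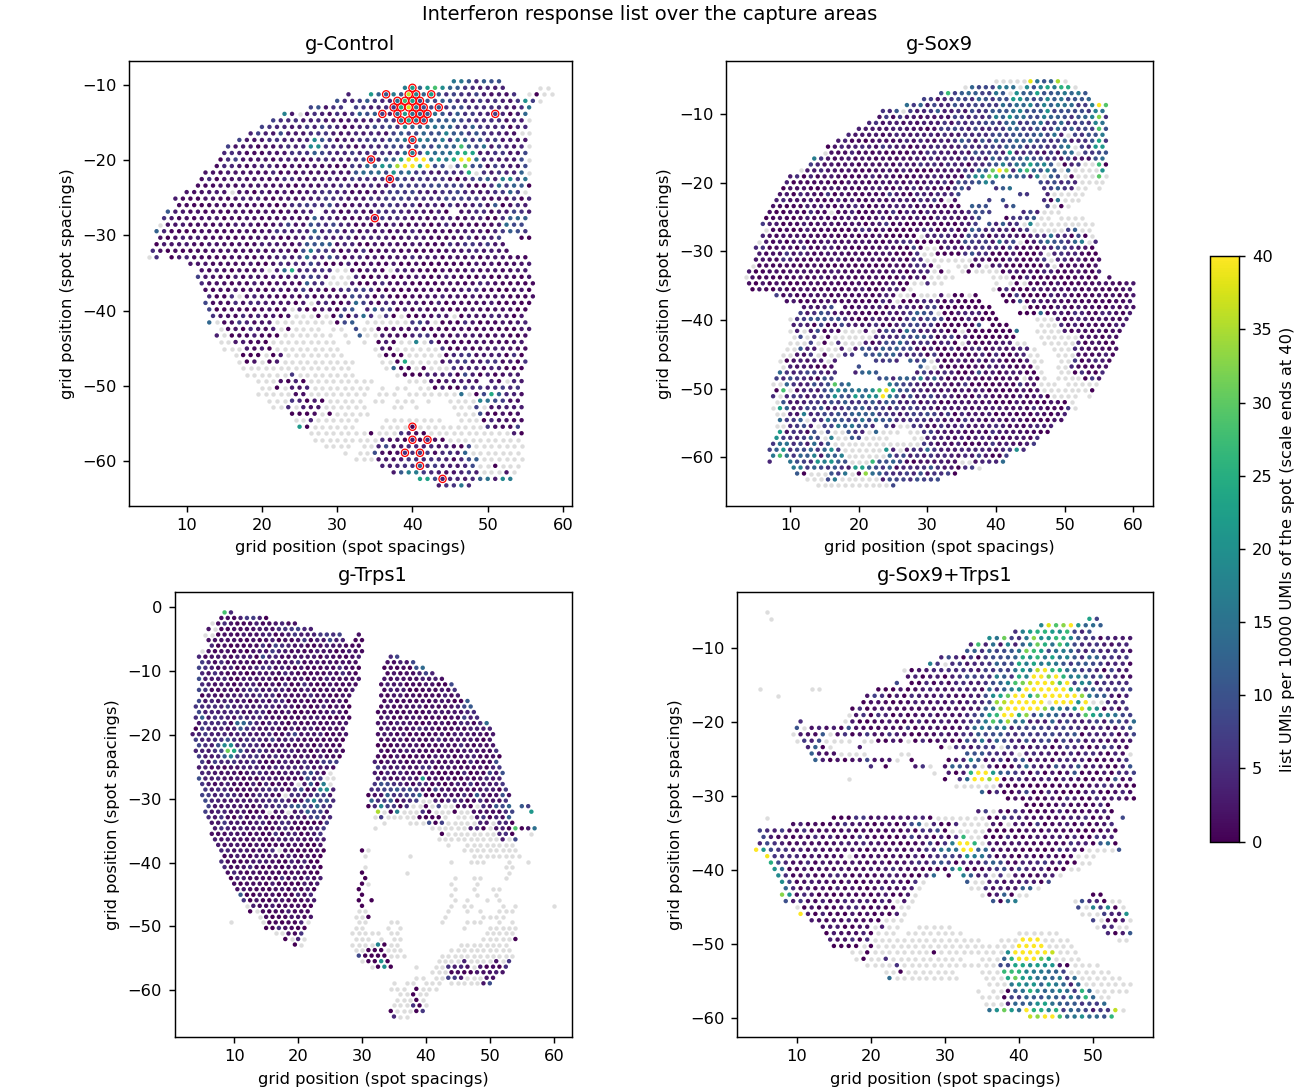
Interferon response UMIs per 10000 UMIs of each spot over the sections of the 4 libraries, with axes in spot spacings, a colour scale that ends at 40, low-UMI spots in grey and red rings on spots with a control-guide UMI. Bright spots cluster in parts of the sections, and the 99th percentile over thinned cortical spots is 67.0 in g-Sox9+Trps1 and 22.9 in g-Control.

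Log2 folds over g-Control were correlated across genes between the guide libraries. Between g-Sox9 and g-Trps1 Pearson's r was 0.656 (10497 genes, covariance 0.0357), between g-Sox9+Trps1 and g-Sox9 0.612 (10468 genes, 0.0418), and between g-Sox9+Trps1 and g-Trps1 0.393 (10315 genes, 0.0240). Genes are not independent replicates, and a shared control alone gave 0.555 (covariance 0.0129), 0.499 (0.0129) and 0.490 (0.0126) in simulations of unchanged libraries with the spread seen between sections. With a different g-Control section for each library, r ranged over 0.243 to 0.296, 0.303 to 0.331 and 0.0846 to 0.163. The covariances then ranged over 0.0189 to 0.0231, 0.0282 to 0.0315 and 0.00698 to 0.0138. Each library then had 1 g-Control section, so part of each correlation may come from the shared g-Control library. A single section has fewer UMIs, and its counting noise also lowers r, so the fall in r does not measure that part.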

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

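The counts around the control guide, the sex test, the injection-site test and the tests in thalamus, habenula and striatum, in the form given here, were chosen only after their results were seen, the other tests given here before.

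A signal outside the measured genes was the control guide sequence itself, which was carried as a feature of the tables. The g-Control library held 68 UMIs of it in 37 spots, 2.47 CPM of all genes' UMIs, 30 of the spots in section A and 7 in section B, and 15 of them in layer 5, 9 in meninges, 8 in layers 2 and 3 and the rest in layer 6, layer 4 and hippocampus. The g-Sox9 and g-Trps1 libraries held 0 and g-Sox9+Trps1 held 1, while the 6 features of targeting guides held 0 UMIs in all 4 libraries, which allows up to 0.109, 0.127, 0.129 and 0.243 CPM. In section A of g-Control, 137 cortical spots within 8 spot spacings of the centre of the guide spots were set against 544 farther ones. Gfap was 3.41-fold, Vim 2.57-fold, Aif1 2.51-fold and Cd68 1.86-fold higher near the guide, interferon genes 3.23-fold, complement genes 2.68-fold, antigen presentation genes 2.65-fold, homeostatic microglia 2.20-fold and reactive astrocyte genes 1.81-fold, and homeostatic astrocyte genes were at 0.981-fold. Sox9 and Trps1 were at 0.918-fold and 0.764-fold there, with intervals that include 1, and no such place can be marked in the other libraries. How much of such tissue the cortical spots of each library held is therefore not known. A different share could move these lists between libraries, which was not tested for g-Sox9 and g-Trps1.

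Interferon response and antigen presentation genes were higher in g-Sox9+Trps1 than in g-Control. Thinning every library to equal depth gave a median interferon log2 fold of 0.91. Thinning all genes of a library at the same rate leaves expected folds unchanged, so it cannot decide whether shallower sequencing is the cause. The sex of the animals as sole cause is argued against by a median of 1.70 over g-Trps1, also male. More of the injection site in these sections stays open. In cortical spots reactive astrocyte genes had a summed fold of 1.01, homeostatic microglia 1.02 and activated microglia 1.07, but the activated microglia median was 0.33, and in white matter the summed folds were 1.40, 1.62 and 1.43. Differences between animals or in virus dose and an effect of the guides were not tested, and Trps1 was not detectably lower in this library.

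Immediate early genes were lower in g-Sox9 and g-Trps1 than in g-Control. A different layer make-up is argued against by medians of -0.90 in g-Sox9 and -0.44 in g-Trps1 with equal weight per cortical cluster. In thalamus, habenula and striatum together, away from the injected cortex, medians over 21 genes were -0.44 and -0.45, but g-Sox9 held 344 striatal and 179 thalamic spots against 82 and 265 in g-Control. Taken alone, thalamus and habenula gave 0.18 in g-Sox9 and -0.31 in g-Trps1, and striatum -1.17 and -0.66. A state of the whole animal, such as handling before death, could thus account for g-Trps1, is not decided for g-Sox9, and cannot be told apart there from an effect of the guides, which was not tested. The sections of g-Sox9 also passed through other regions, with 21 hippocampal spots against 287 in g-Control. Whether its cortical spots came from other cortical areas was not tested.

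Among genes apart in g-Sox9+Trps1, 27 were lower than in each other library, 18 of them, Gstp1 and Erh included, also by the section condition. Thinning every library to equal depth gave these genes a median of -0.86 over g-Control, beside -0.79 as sequenced. The genes were chosen for low values in these same counts, and thinning keeps expected folds. Thinning therefore cannot decide on shallower sequencing as a cause. A cause that acts on the whole library is a candidate explanation, since 26 of these genes had a median of -0.63 in thalamus, habenula and striatum, where all genes had -0.03, and medians of -0.73 and -0.71 in thalamus and habenula and in striatum alone. Reads shared with near-identical copies and an effect of the guides were not tested.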

How the results depend on the processing

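The minimum of 3000 UMIs per cortical spot, the section condition on genes apart, the rule for when a list median counts as moved, and the choice of reactive astrocyte, interferon and antigen presentation genes for full values of the focus and the spread were made after seeing the data. No paired analysis was possible because each group has 1 library. Leaving aside left-out sections, of 4820 values of named genes' folds under the alternatives 4430 stayed within their interval and 390 moved, and no gene that met the 1.5-fold rule turned direction, and of 2010 list medians 1762 stayed within the range of their section pairings, 242 moved and 6 turned, counting turns only for lists outside the random lists. Of 240 counts of genes 159 stayed within 1.5 times the main count, and the 3 correlations of folds were 0.760 (g-Sox9 and g-Trps1), 0.763 (g-Sox9+Trps1 and g-Sox9) and 0.479 (g-Sox9+Trps1 and g-Trps1) with at least 500 UMIs per gene, where a shared control alone gave 0.579, 0.549 and 0.542 in simulations with the spread between sections. The covariances were 0.0376, 0.0457 and 0.0220 against 0.00876, 0.00876 and 0.00860 in those simulations. Interferon and antigen presentation medians of g-Sox9+Trps1 over each other library, and immediate early medians of g-Sox9 and g-Trps1 over g-Control, kept their sign under every alternative run. The g-Sox9+Trps1 library had the fewest UMIs, and 0 UMIs allow 0.411 CPM there. Counts of genes below are given as higher and lower for g-Sox9, g-Trps1 and g-Sox9+Trps1 over g-Control, g-Sox9+Trps1 over g-Sox9, g-Sox9+Trps1 over g-Trps1 and g-Sox9 over g-Trps1, then as genes apart in g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1. Fold sizes and gene minimums move them by construction, and for other moves the cause was not tested.

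With the smaller fold of the section condition in place of 1.5, the counts were 141 and 189, 57 and 90, 147 and 217, 132 and 125, 176 and 216, 110 and 131, then 110, 109, 119 and 314. At 2-fold they were 8 and 27, 6 and 17, 27 and 24, 33 and 7, 47 and 26, 18 and 10, then 3, 7, 11 and 21. With at least 20 UMIs per gene they were 192 and 213, 94 and 143, 205 and 249, 218 and 250, 268 and 264, 191 and 142, then 86, 124, 110 and 308. With at least 500 they were 5 and 46, 2 and 16, 12 and 47, 22 and 10, 22 and 43, 5 and 26, then 3, 8, 5 and 20. Over all tissue spots, whose regions differ between libraries, they were 190 and 210 for g-Sox9 over g-Control, 116 and 166 for g-Sox9+Trps1 over g-Sox9, 178 and 101 for g-Sox9 over g-Trps1, and 20, 199 and 133 apart in g-Control, g-Sox9 and g-Sox9+Trps1. There the fibroblast median of g-Sox9+Trps1 over g-Sox9 turned to -0.084 and the blood median of g-Sox9 over g-Trps1 to -0.042. With equal weight per cluster 65 and 45 genes were higher in g-Sox9 and g-Trps1 than in g-Control, and medians turned to 0.040 for homeostatic microglia in g-Sox9 over g-Control, -0.016 for myelin in g-Sox9+Trps1 over g-Trps1 and -0.25 for blood in g-Sox9 over g-Trps1. With equal weight per spot 58, 32 and 88 genes were higher in g-Sox9, g-Trps1 and g-Sox9+Trps1 than in g-Control, without the section condition 29 in g-Trps1, with that condition applied to genes apart 13 and 11 were apart in g-Sox9 and g-Trps1, and with listed genes kept in the clustering the fibroblast median of g-Trps1 turned to -0.0055.

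Leaving out 1 section leaves 2 pairings in place of 4, so counts of higher and lower genes go up partly by construction. They ran from 32 to 402 higher and 102 to 300 lower in g-Sox9 over g-Control, 14 to 301 and 58 to 206 in g-Trps1 over g-Control, and 70 to 241 and 117 to 230 in g-Sox9+Trps1 over g-Control, the highest without g-Control section A except 230, without g-Sox9+Trps1 section B. They ran from 71 to 157 and 37 to 180 in g-Sox9+Trps1 over g-Sox9 and 94 to 165 and 82 to 273 in g-Sox9+Trps1 over g-Trps1, the highest without g-Sox9+Trps1 section B, and 34 to 150 and 70 to 89 in g-Sox9 over g-Trps1, the highest without g-Trps1 section A and g-Sox9 section B. Genes apart, which have no section condition and so do not rise for that reason, ran from 7 to 279 in g-Control, 15 to 26 in g-Sox9, 15 to 83 in g-Trps1 and 53 to 179 in g-Sox9+Trps1. The Trps1 fold of g-Sox9+Trps1 over g-Control ran from 0.650 to 1.06. With a section left out, 15 of 97 medians outside the random lists and 72 of 104 inside them turned, and 73 of the 97 turned or moved by over 1.5 times. Those outside ran, in g-Sox9 over g-Control, from -0.065 to 0.38 for mural cells, -0.36 to 0.48 for blood, -0.25 to 0.51 for antigen presentation and -0.20 to 0.076 for homeostatic microglia. In g-Trps1 over g-Control they ran from -0.31 to 0.47 for fibroblasts, -0.51 to 0.41 for blood and -0.38 to 0.0091 for reactive astrocytes, and in g-Sox9+Trps1 over g-Control from -0.091 to 0.017 for synaptic components. In g-Sox9+Trps1 over g-Sox9 they ran from -0.0081 to 0.43 for myelin, -0.12 to 0.0054 for excitatory neurons and -0.087 to 0.43 for fibroblasts, in g-Sox9+Trps1 over g-Trps1 from -0.15 to 0.0013 for resting astrocytes, -0.10 to 0.014 for extracellular matrix (-0.13 with both sections) and -0.068 to 0.38 for myelin, and in g-Sox9 over g-Trps1 from -0.046 to 0.32 for homeostatic microglia. Of those inside, over g-Control, fibroblasts ran from -0.51 to 0.17 in g-Sox9 and -0.27 to 0.51 in g-Sox9+Trps1, choroid plexus from -0.19 to 0.98 in g-Trps1, interferon from -0.12 to 0.31 in g-Sox9 and lymphocytes from -0.21 to 1.06 in g-Sox9 and -0.58 to 0.27 in g-Trps1.

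With 10% of spots as the focus, reactive astrocyte values were 1.16 in g-Control and 0.96 in g-Trps1, antigen presentation 1.39 in g-Control and 1.63 in g-Sox9, and heat shock genes turned to 0.0027 in g-Control. With 2%, reactive astrocyte values were 1.67, 1.08, 1.65 and 1.64 in g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1, antigen presentation 1.69, 1.94, 1.21 and 2.29, and interferon 1.72 in g-Control. Resting astrocytes, immediate early genes and metallothionein turned to 0.045, -0.010 and 0.011 in g-Sox9+Trps1 and fibroblasts to 0.083 in g-Trps1. With spots taken alone, reactive astrocyte values were 0.75 in g-Sox9 and 0.95 in g-Trps1, interferon 1.60, 1.38 and 2.22 and antigen presentation 1.58, 1.17 and 1.92 in g-Sox9, g-Trps1 and g-Sox9+Trps1. Resting astrocytes and metallothionein turned to 0.019 and 0.064 in g-Sox9+Trps1, and inhibitory neurons, immediate early genes and fibroblasts to 0.021, -0.018 and 0.059 in g-Trps1. The 99th percentile of antigen presentation over spots was 27.9 in g-Control and 16.0 in g-Trps1 without thinning.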

Other observations

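The levels by region given here were chosen only after the data were seen, and no test is reported with them. Several lists not described above lay inside the random lists in all 3 guide libraries over g-Control, with medians given in the order g-Sox9, g-Trps1 and g-Sox9+Trps1. Astrocyte transcription factors had medians of -0.04, 0.00 and -0.05, inhibitory neurons 0.00, -0.03 and 0.04, oligodendrocyte precursors 0.00, 0.09 and 0.02, neurogenesis -0.01, 0.08 and -0.04, p53 and DNA damage 0.04, -0.02 and 0.07, endoplasmic reticulum stress 0.00, 0.03 and 0.01, heat shock 0.00, -0.01 and 0.03 and ependymal genes 0.10, 0.07 and -0.06. Cholesterol and lipid synthesis genes had -0.01, -0.03 and 0.13, also inside, and were at 0.18 and 0.16 in g-Sox9+Trps1 over g-Sox9 and over g-Trps1, above the random lists in both. Lymphocyte and neutrophil genes had 0.34 in g-Sox9 and -0.08 in g-Trps1, whose signs both turned with single sections left out (-0.21 to 1.06 and -0.58 to 0.27), and too few members with 20 UMIs for a median in g-Sox9+Trps1.

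In white matter the complement genes, which tag material for removal by microglia, stood at 1221, 1155, 940 and 2319 CPM in g-Control, g-Sox9, g-Trps1 and g-Sox9+Trps1, homeostatic microglia genes at 2395, 2225, 1971 and 3891 CPM and antigen presentation genes at 1170, 1240, 708 and 2990 CPM. In the meninges, antigen presentation genes stood at 2488, 3448, 1470 and 5848 CPM, and interferon genes at 1242, 1433, 654 and 2212 CPM. In the striatum, which held 82, 344, 71 and 86 spots, interferon genes stood at 266, 162, 167 and 208 CPM and antigen presentation genes at 421, 379, 319 and 319 CPM, so that in neither list was g-Sox9+Trps1 the highest library there.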
